A study of Mus musculus with 9 samples.

How the data were processed

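Gene expression was measured in 9 samples of primary mouse calvarial osteoblasts at passage 2, 3 each for vehicle, 100 nM hPTH(1-34) and 1 µM bPTH(7-34). Per the labels, differentiation started on day 3, cells were deprived of serum for 24 h on day 10 and treated for 4 h, and 100 ng of RNA was used on Affymetrix Mouse Gene 2.0 ST arrays. The series text says that cells were prepared independently for each replicate, but not whether one preparation was divided among the treatments. The deposited values are log2 RMA expression per transcript cluster, which the authors made with Affymetrix Expression Console and RMA (versions not stated), rounded to 2 decimals. No scanner files were used, and the array medians were close but not identical.

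The value table held 41345 transcript clusters. The probe annotation gave exactly 1 gene symbol for 23521 of them, several for 1814 and none for 16010. Of the 23521, 23328 had a gene identifier in the RefSeq table, and 0 of these had another symbol there. That table served for names alone. The tests used the 23521 clusters with 1 symbol, and a gene with several clusters (1082 genes) was read from the one with the highest mean over the 9 arrays. Arrays have no read depth, and the number of arrays limits the precision.

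Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), in a single fit of all 9 arrays with group as the only term, two-sided, with Benjamini-Hochberg adjustment within each of 3 comparisons and a threshold of 0.05. The fit had 6 residual degrees of freedom and 3.20 prior degrees of freedom. Any difference among the 3 groups was tested with the moderated F-test. Errors beside log2 changes are standard errors from this fit, errors beside levels are standard deviations of 3 arrays, and 95% intervals come from the fit. Fold values of falls are given as sizes. Leaving out one array leaves 2 in its group, with the spread pooled over the groups.

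A total of 31 gene lists, with 623 of 674 entries and 581 of 630 genes measured, covered cAMP and receptor signalling, bone, growth factor, stress and metabolic pathways, and markers of other cell types. They were tested with camera (preset correlation 0.01) on 1 cluster per gene, adjusted over the lists within a comparison, with camera with an estimated correlation and fry as alternatives. fry tests whether the genes of a list move on balance in one direction, its mixed version whether they change in either direction, and neither compares a list with other genes. With an estimated correlation no list passed in any comparison. Relations between the changes of both peptides were set against 100 simulated sets of unchanged groups that shared the vehicle arrays, and bootstrap intervals used 2000 draws of genes, which treats genes as independent.

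The tests, lists, most alternatives and the rule for named genes were chosen before the data were examined. The rule took, per comparison, the 10 largest rises and 10 largest falls among genes past 0.05 whose groups did not overlap, passing over predicted and small RNA genes, or the 5 smallest p where fewer than 5 passed. It added up to 4 members per list with the smallest p for hPTH(1-34) against vehicle, up to 2 in the other comparisons, and 15 fixed genes. Fixed gene Runx2 has no cluster with a single symbol and was not analysed here.

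Alternatives were the array number as a fixed or random block, all clusters, clusters with a mean log2 of at least 5, quantile normalisation, a shift of the arrays to one median, a trended and robust eBayes, array weights, 1 cluster per gene, a 2-fold threshold, the 6 arrays of a comparison alone, and each array left out. A filter at a mean log2 of at least 3, and a split of the vehicle arrays between the peptides, were added after seeing the data. The fit without a block was set before the data were seen. The array number was to replace it as a block if all pairs of arrays with one number correlated above 0.1, which they did not, so the block stayed an alternative. The counts of the 3 comparisons with the block had been seen in the same output as the first of these correlations, and before the set of clusters for the check was chosen, so this decision was not blind to them. The tests were checked on 20 simulated sets of 23521 clusters with 200 changed. Of the changes of 1 on the log2 scale 86.9% were recovered for hPTH(1-34) against vehicle, of those of 0.5 14.9% and of those of 2 99.6%, and 4.31% of the calls were false. camera called a list raised by 0.5 in 20 of 20 sets, and 2 of 600 unchanged lists. The simulated arrays were drawn independently, without the correlation of arrays with one number, so these shares need not hold for the data. The simulated genes were drawn independently too. This check therefore says nothing on false calls for lists of correlated genes, such as interferon response (estimated correlation 0.765) or adipocyte markers (0.451). Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.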

Results

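RNA levels were measured on 9 microarrays of primary osteoblasts, the bone-forming cells, taken from the skull caps of C57BL/6J mice aged 7 to 10 days. The cells were kept for 4 h with vehicle, with 100 nM human parathyroid hormone fragment hPTH(1-34), or with 1 µM of a bovine fragment, bPTH(7-34), and each group had 3 arrays. hPTH(1-34) is an agonist of the parathyroid hormone receptor Pth1r, which raises cAMP. bPTH(7-34) lacks the residues before position 7 and carries D-tryptophan at residue 12 and tyrosine at residue 34. It is known as an antagonist of that receptor for the rise of cAMP. Other actions through the receptor are not excluded by that name, and only RNA was measured here. The peptides were given at different doses, so their values stand side by side and no matched-dose difference can be had. The table held 41345 transcript clusters (probe groups for one transcript region) per array, with array medians from 1.67 to 1.76 on the log2 scale. Correlations across all clusters ran from 0.977 to 0.982 between arrays of a group and from 0.972 to 0.985 between arrays of different groups. The 23521 clusters with a single gene symbol were tested, and they stood for 22180 genes. With 3 arrays per group, the number of arrays limits the precision. The arrays give no read depth and the table no detection calls. As a limit of background, chosen after the data were seen, the 95th percentile of the vehicle means of 1105 olfactory receptor genes, which are not expected in osteoblasts, was 1.69 on the log2 scale.

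The first comparison asked which genes differed after hPTH(1-34). The strongest rise was in Dgat1, the enzyme of the last step of triglyceride synthesis, at 13.1-fold (log2 change 3.71 ± 0.26 SE, n = 3 per group, adjusted p = 0.00287). Its mean log2 level was 4.53 ± 0.09 (SD) with vehicle, 8.24 ± 0.58 with hPTH(1-34) and 4.86 ± 0.26 with bPTH(7-34). Tnfsf11, which encodes the osteoclast differentiation factor RANKL, rose 5.95-fold (2.57 ± 0.43, adjusted p = 0.0468), and Vdr, the vitamin D receptor, rose 4.68-fold (2.23 ± 0.22, adjusted p = 0.00861). Nr4a3, a cAMP-induced orphan nuclear receptor, rose 6.93-fold (2.79 ± 0.23, adjusted p = 0.00556). Among the falls, Rspo2, a secreted enhancer of Wnt signalling, was 2.89-fold lower (log2 change -1.53 ± 0.23, adjusted p = 0.0356). Bmp4, a bone morphogenetic protein, was 2.66-fold lower (-1.41 ± 0.24, adjusted p = 0.0484).

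Other leading rises were in Kcnk10, a background potassium channel (log2 change 2.79 ± 0.42), Ramp3, a partner of calcitonin-family receptors (2.57 ± 0.36), and Dgkh, a diacylglycerol kinase (2.16 ± 0.32). Ugdh, which makes UDP-glucuronic acid for glycosaminoglycans, rose by 2.12 ± 0.24, the Cdc42 activator Dock9 by 2.10 ± 0.25, and the chondroitin sulfotransferase Chst11 by 1.96 ± 0.31. Adjusted p of these 6 genes ran from 0.0127 to 0.0378. Lower levels were measured for Lbh (-1.15 ± 0.15), the insulin receptor substrate Irs1 (-1.13 ± 0.19), the orphan receptor Gpr176 (-1.11 ± 0.16) and Calhm5 (-1.10 ± 0.18). The cytokine receptor Lifr (-1.05 ± 0.14), Klhl24 (-0.98 ± 0.15), the zinc finger gene Zfp521 (-0.95 ± 0.13) and Snx7 (-0.94 ± 0.15) were lower as well, and adjusted p of these 8 genes ran from 0.0237 to 0.0468. With vehicle, Nr4a3 (2.17 ± 0.11 SD), Ramp3 (2.00 ± 0.06) and Kcnk10 (2.40 ± 0.20) lay little above the background limit of 1.69, so the sizes of their rises rest on a level near background. A dimmer Irs1 cluster gave -0.21 ± 0.17 (adjusted p = 0.753).

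**Figure D1:**
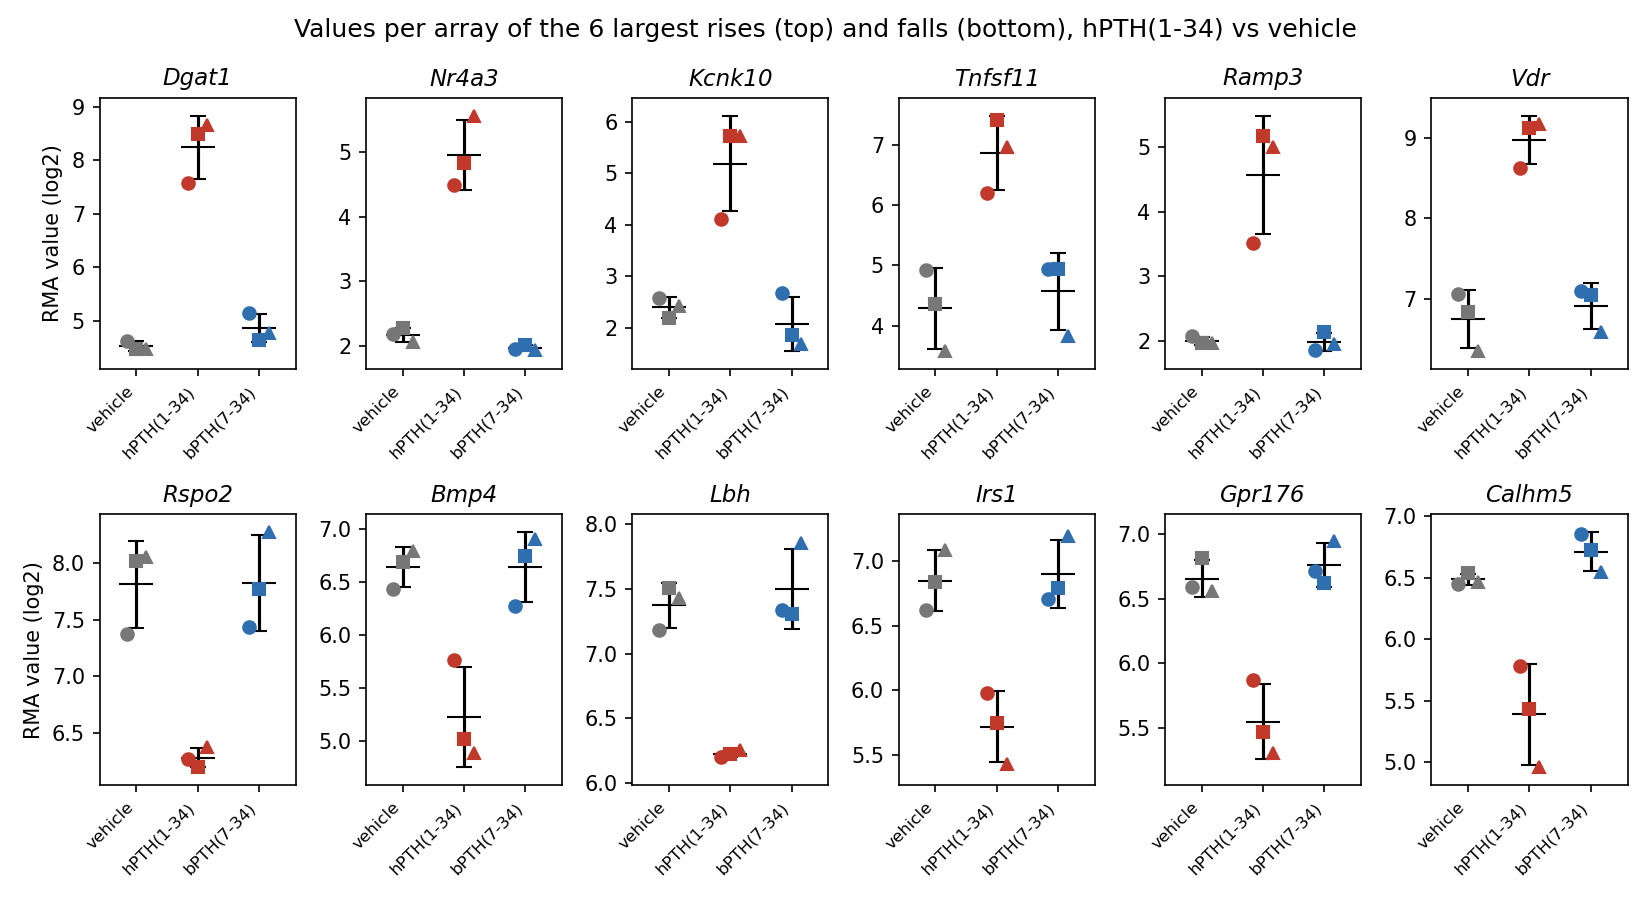
Log2 RMA expression (vertical axis) on each of the 9 arrays for 12 genes, by group, with circles, squares and triangles for arrays numbered 1, 2 and 3 and black bars for the mean ± SD of 3 arrays. Dgat1 lay at 4.53 ± 0.09 with vehicle and 8.24 ± 0.58 with hPTH(1-34), while Rspo2 went from 7.81 ± 0.38 to 6.28 ± 0.09.

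In all, 106 clusters passed the adjusted p threshold of 0.05 between hPTH(1-34) and vehicle, 73 higher and 33 lower, and 60 of them (52 higher, 8 lower) differed at least 2-fold. For 1 of the 106 both groups lay under the background limit, for 1 hPTH(1-34) alone and for 3 vehicle alone. For each of the 106, the 3 arrays of one group lay beyond the 3 of the other. Such a separation was seen for 10.7% of all tested clusters, where chance gives 10% for independent arrays. At an unadjusted p under 0.05 there were 2189 clusters, against 1176 by chance, again for independent arrays. The count depended on single arrays. Without vehicle array 1, 2 or 3 it was 72, 0 and 0 in limma, with 2454, 1798 and 1927 clusters at an unadjusted p under 0.05. Without hPTH(1-34) array 1, 2 or 3 it was 259, 3 and 2. Of the 31 named genes that passed, 14, 0 and 0 still passed without vehicle array 1, 2 and 3, and 30, 2 and 2 without hPTH(1-34) array 1, 2 and 3. In each of these fits all 106 clusters kept an unadjusted p under 0.05 in limma. The median size of their log2 changes ran from 1.02 to 1.15, against 1.095 with all arrays. The 106 were chosen on the same arrays, so this is no independent support. With the array number as a block, 22 of the 31 still passed, and Kcnk10, Chst11, Bmp4, Irs1, Snx7, Crem, Inhba, Vcl and Scx did not (adjusted p from 0.0518 to 0.0853). A limma fit of the 6 arrays of these groups alone called 0 clusters, with 1936 at an unadjusted p under 0.05, and a fit of all 41345 clusters called 16. Subtracting arrays of the same number, the median signed change of the 106 clusters was 0.73 for number 1, 1.22 for number 2 and 1.25 for number 3. As the groups do not overlap in these clusters, their direction without an array or within a number was fixed by that choice.

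Of 24 measured genes in the list of cAMP/CREB targets, 4 rose, 0 fell and 20 did not pass, and adjusted over the list alone 10 rose. The 4 were Nr4a3, its relative Nr4a2 (1.81 ± 0.21, adjusted p = 0.0149), Rgs2, which dampens G protein signals (1.36 ± 0.21, adjusted p = 0.0377), and Crem, a cAMP-responsive transcription factor (0.67 ± 0.11, adjusted p = 0.0442). With vehicle, Crem (2.16 to 2.3) also lay little above the background limit of 1.69. The list as a whole was higher by camera (adjusted p = 1.90e-06), with adjusted p = 0.179 with an estimated correlation. In the list of receptor and cAMP pathway feedback genes, 4 of 31 rose, 0 fell and, adjusted over the list alone, 6 rose. They were Ramp3, Rgs2, Crem and the phosphodiesterase Pde10a (1.09 ± 0.15, adjusted p = 0.0244), so Rgs2 and Crem count in both lists. This list was higher by camera (adjusted p = 0.00156), with adjusted p = 0.179 with an estimated correlation. In the list of mineral and phosphate handling genes, Vdr alone of 16 rose, and adjusted over the list alone 3 rose and 0 fell. The list was higher (camera adjusted p = 0.00270), with adjusted p = 0.294 with an estimated correlation, and Alpl, the mineralisation phosphatase, gave 0.97 ± 0.17 (adjusted p = 0.0601). These 3 calls held in each fit without a single array, and fry, a test of whether a list moves on balance in one direction, gave adjusted p = 0.0289 for each.

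Adipocyte markers were higher as a list of 11 (camera adjusted p = 0.00309), with 10 positive changes and a median of 0.38, although 0 members passed, also when adjusted over the list alone. Fabp4, a fatty acid binding protein, gave 0.85 ± 0.26 (adjusted p = 0.299) and the lipid droplet protein Plin1 0.54 ± 0.21 (adjusted p = 0.454). The list had adjusted p = 0.872 with an estimated correlation, and adjusted p = 0.116 by camera without hPTH(1-34) array 1. Cytoskeleton and SRF/YAP targets were lower as a list of 17 (camera adjusted p = 0.00309), with 3 positive changes and a median of -0.24. In it Vcl, the adhesion protein vinculin, fell (-0.60 ± 0.09, adjusted p = 0.0380), and adjusted over the list alone 2 fell and 1 rose. The calponin gene Cnn1 gave 2.03 ± 0.52 (adjusted p = 0.202), against the direction of the list. The list had adjusted p = 0.789 with an estimated correlation, and adjusted p = 0.195 by camera without hPTH(1-34) array 1. Interferon response genes were lower as a list of 19 (camera adjusted p = 0.00309), with 2 positive changes, and 0 members passed, while 1 fell when adjusted over the list alone. Ifit2, an interferon-induced antiviral gene, gave -0.87 ± 0.19 (adjusted p = 0.118). This list had adjusted p = 0.880 with an estimated correlation, and its call was lost without vehicle array 1 (0.493), hPTH(1-34) array 2 (0.0861) or hPTH(1-34) array 3 (0.413). All 6 lists kept the sign of their median when the arrays were scaled to one median or quantile normalised again.

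**Figure D2:**
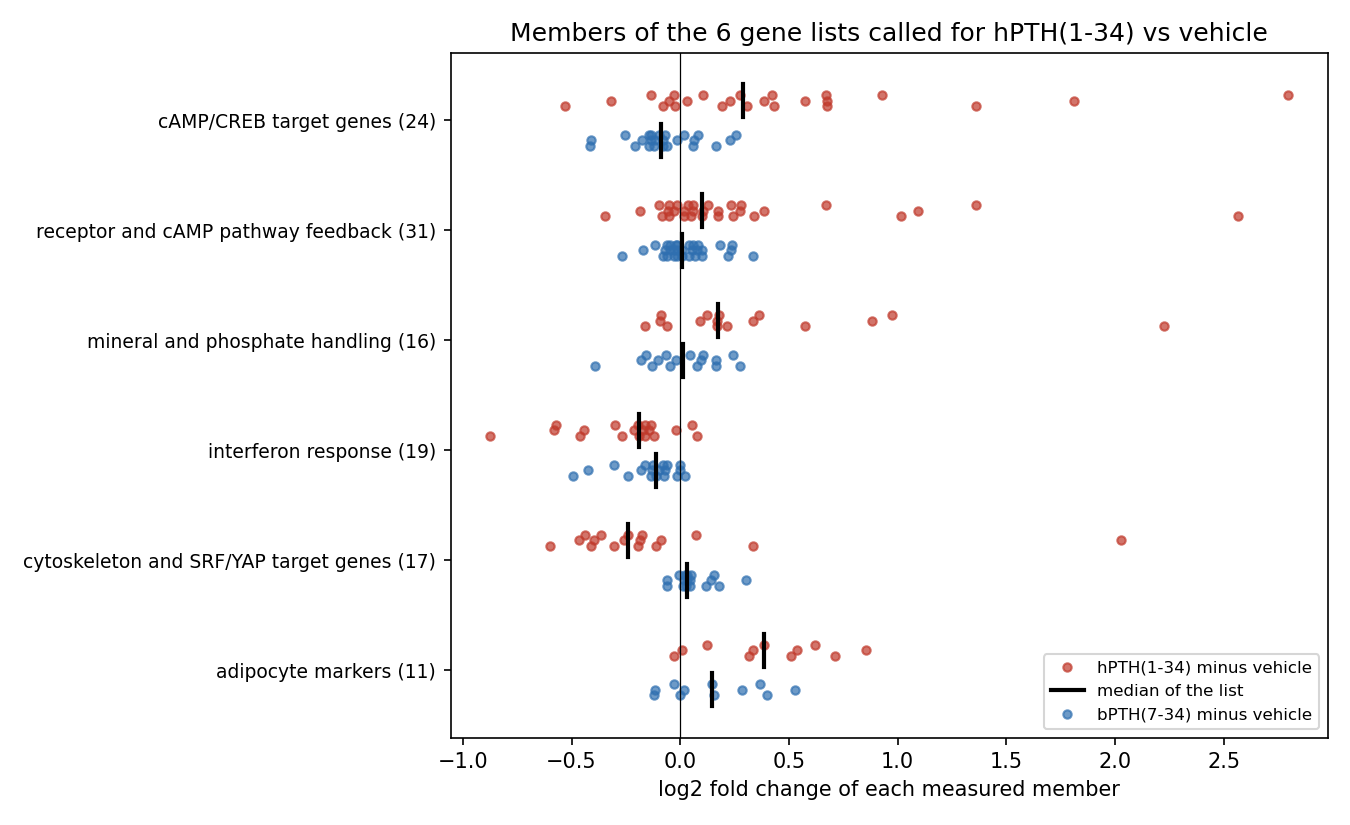
Log2 change against vehicle (axis in log2 units) of each measured member of the 6 lists called for hPTH(1-34), in red for hPTH(1-34) and in blue for bPTH(7-34), each point a gene and each black bar the list's median. The hPTH(1-34) median was 0.29 for the cAMP/CREB targets, 0.38 for adipocyte markers, -0.24 for cytoskeleton and SRF/YAP targets and -0.19 for interferon response genes, against -0.09, 0.15, 0.03 and -0.11 for bPTH(7-34).

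Single members of other lists passed without a call for the list. In the list of Wnt ligands, receptors and antagonists, Rspo2 alone of 39 fell, and adjusted over the list alone 4 fell (camera adjusted p = 0.611). Its member Rspo3, a relative of Rspo2, gave -0.997 ± 0.21 (adjusted p = 0.0990) and the Wnt receptor Fzd5 -1.45 ± 0.31 (adjusted p = 0.108). Of 18 Wnt/beta-catenin targets 0 passed and 1 fell when adjusted over the list alone (camera adjusted p = 0.351), and Lgr5, an R-spondin receptor, gave -1.43 ± 0.25 (adjusted p = 0.0561). In the TGF-beta and BMP axis of 32 genes, the activin subunit Inhba rose (1.25 ± 0.20) and Bmp4 fell, and adjusted over the list alone 4 rose and 4 fell (camera adjusted p = 0.906). Among 21 osteoclast-regulating factors Tnfsf11 alone rose, also when adjusted over the list alone (camera adjusted p = 0.876). In that list Il6 gave 1.25 ± 0.41 (adjusted p = 0.358), Csf1 -0.54 ± 0.21 (0.461) and Tnfrsf11b, the RANKL decoy receptor, -0.07 ± 0.16 (0.934). In 25 matrix proteases and inhibitors, the urokinase receptor gene Plaur rose (1.47 ± 0.23), and adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.803).

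In the IGF axis of 15 genes Irs1 alone fell, also adjusted over the list alone (camera adjusted p = 0.876). In 27 NF-kB and cytokine genes the interleukin receptor gene Il4ra alone rose (1.25 ± 0.18), also adjusted over the list alone. That list had camera adjusted p = 0.169, but 7.81e-05 without hPTH(1-34) array 1 and 0.0224 without vehicle array 3, towards lower levels, and 0.0180 with the array number as a block. In 21 glycolysis genes Pdk4, a brake on pyruvate use, fell (-0.93 ± 0.14), and adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.868). In 19 cholesterol biosynthesis genes Pmvk, a mevalonate pathway kinase, rose (1.63 ± 0.23), and adjusted over the list alone 2 rose (camera adjusted p = 0.563). Among 14 fibroblast and periosteal progenitor markers the tendon transcription factor gene Scx fell (-0.66 ± 0.10), and adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.611).

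No member passed over all genes in the remaining lists. Adjusted over the list alone, 4 of 32 FGF, EGF and angiogenic factors rose (camera adjusted p = 0.657), 3 of 18 hypoxia and HIF targets rose (0.365), 4 of 17 circadian clock genes rose and 3 fell (0.790), and 2 of 19 Notch genes fell (0.611). Vegfa, an angiogenic factor, gave 1.07 ± 0.20 (adjusted p = 0.0691). Adjusted over the list alone, 1 gene rose among 20 unfolded protein and ATF4 response genes (camera adjusted p = 0.249, but 0.0469 without hPTH(1-34) array 3), 22 osteoblast differentiation and matrix genes (0.611), 32 cell cycle genes (0.685) and 13 chondrocyte markers (0.685). In the other lists 0 passed by limma in either way, namely 12 osteocyte genes (camera adjusted p = 0.765), 22 MAPK/ERK immediate early and feedback genes (0.611), 13 endothelial markers (0.611), 14 skeletal muscle markers (0.657), 9 blood cell markers (0.790) and 11 housekeeping genes (0.611). The same held for 20 macrophage and osteoclast markers (camera adjusted p = 0.611, but 0.0118 without hPTH(1-34) array 1). Median and mean differed in sign for the Wnt ligand, osteoclast-regulating, osteocyte, matrix protease, FGF, circadian and fibroblast lists. Of the genes named in advance, Col1a1, the main collagen of bone, gave 0.00 ± 0.11, Pth1r -0.35 ± 0.19 and Igf1 0.53 ± 0.28, and none of these passed. Mmp13 gave -0.13 ± 0.18 and Ptgs2 -0.14 ± 0.57, and none of these passed either. Bglap, which encodes osteocalcin, and Sost lay under the background limit in all 3 groups, as did each of the 9 blood cell markers, so no change could be measured for them. Runx2 was not analysed here.

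The second comparison asked which genes differed after bPTH(7-34). No gene passed. With each gene read from its brightest cluster, the smallest p values belonged to P2ry6, a nucleotide receptor gene (log2 change -0.58 ± 0.09, n = 3 per group), the olfactory receptor genes Olfr706 (-0.63 ± 0.10) and Olfr1393 (0.71 ± 0.12), Gm6034 (0.63 ± 0.11) and Prss48 (0.50 ± 0.09). Their adjusted p ran from 0.776 to 0.831. Dimmer clusters of a gene, such as that of Syne1 given below, were not part of this ranking. Olfr706 lay under the background limit in both groups, and Olfr1393 with vehicle. Among the genes fixed in advance that hPTH(1-34) raised, the intervals held 0, with Nr4a2 at -0.14 (95% interval -0.61 to 0.33), Rgs2 at 0.06 (-0.42 to 0.53) and Crem at -0.07 (-0.32 to 0.18). The interval was wider for Tnfsf11, at 0.28 (-0.69 to 1.25), and for another fixed gene, Il6, at -0.46 (-1.39 to 0.47). Tnfrsf11b gave 0.46 (0.10 to 0.82), with adjusted p = 0.999. limma called 0 of 23521 clusters, with 780 at an unadjusted p under 0.05 where chance gives 1176, and it also called 0 without each array in turn. The median half-width of the 95% intervals was 0.30. In simulated data of this size with 200 changed clusters, 87.0% of log2 changes of 1 were recovered, but 19.6% of changes of 0.5. With few changed clusters the adjusted threshold is stricter, so these shares do not hold for a peptide that changes few genes. The simulated arrays also lacked the correlation of arrays with one number. For 5.29% of the clusters the 3 arrays of one group lay beyond the 3 of the other, where chance gives 10%. Both chance values, 1176 and 10%, hold for independent arrays. Arrays of one number correlate, and this fit has no block for the number. That 780 and 5.29% lie under chance is therefore no result about bPTH(7-34).

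No gene list was called for bPTH(7-34) by camera with the preset or the estimated correlation or by fry, and 0 members of any list passed adjusted over the list alone. The smallest adjusted p was 0.134, for glycolysis genes (4 of 21 positive) and interferon response genes (1 of 19 positive), the latter 0.00997 with the array number as a block. Leaving out one array gave calls, 2 without bPTH(7-34) array 1, 6 without bPTH(7-34) array 2, 2 without vehicle array 2 and 3 without vehicle array 3. In these 4 fits glycolysis had adjusted p from 0.0198 to 0.0469 and interferon response from 0.00289 to 0.0469. NF-kB and cytokine genes were called without bPTH(7-34) array 2 (1.49e-04) and vehicle array 3 (0.0198), and macrophage, adipocyte and skeletal muscle markers without bPTH(7-34) array 2 (0.0469 each). The cAMP/CREB targets had a median of -0.09 (camera adjusted p = 0.471) and the receptor and cAMP feedback genes one of 0.01 (0.749). Median, mean and test direction differed for the osteocyte, mineral, matrix protease, IGF, FGF, endothelial, fibroblast and blood cell lists.

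In the 106 clusters called for hPTH(1-34), the median bPTH(7-34) change, signed by the hPTH(1-34) direction, was 0.01 (bootstrap 95% interval -0.02 to 0.05). Of these, 56 had the same direction and 49 the opposite, for 12 the bPTH(7-34) change had an unadjusted p under 0.05, and for 84 its interval excluded 0.5 of the hPTH(1-34) change. In the 109 clusters called between the peptides, the same median was -0.07 (-0.11 to -0.04), with 30 in the same direction and 78 in the opposite. For 107 the interval excluded 0.5 of the hPTH(1-34) change against vehicle. Choosing clusters on arrays shared with vehicle draws the first median up, and choosing them on the difference from bPTH(7-34) draws the other down. The counts of 84 and 107 treat the hPTH(1-34) change as free of error, and the clusters were chosen for large differences. These counts are therefore no test of whether bPTH(7-34) lacks the response. Chosen after its values were seen, Kcne4, a potassium channel subunit, had 1.36 ± 0.17 with hPTH(1-34) (adjusted p = 0.0204) and 0.65 ± 0.17 with bPTH(7-34) (adjusted p = 0.999). A dim cluster of Syne1, a nuclear envelope gene, was chosen in the same way, and went from 2.61 ± 0.25 (SD) with vehicle to under the background limit with hPTH(1-34) (adjusted p = 0.0414) and with bPTH(7-34) (adjusted p = 0.776). The brightest Syne1 cluster gave -0.46 ± 0.23 with hPTH(1-34) (adjusted p = 0.602).

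**Figure D3:**
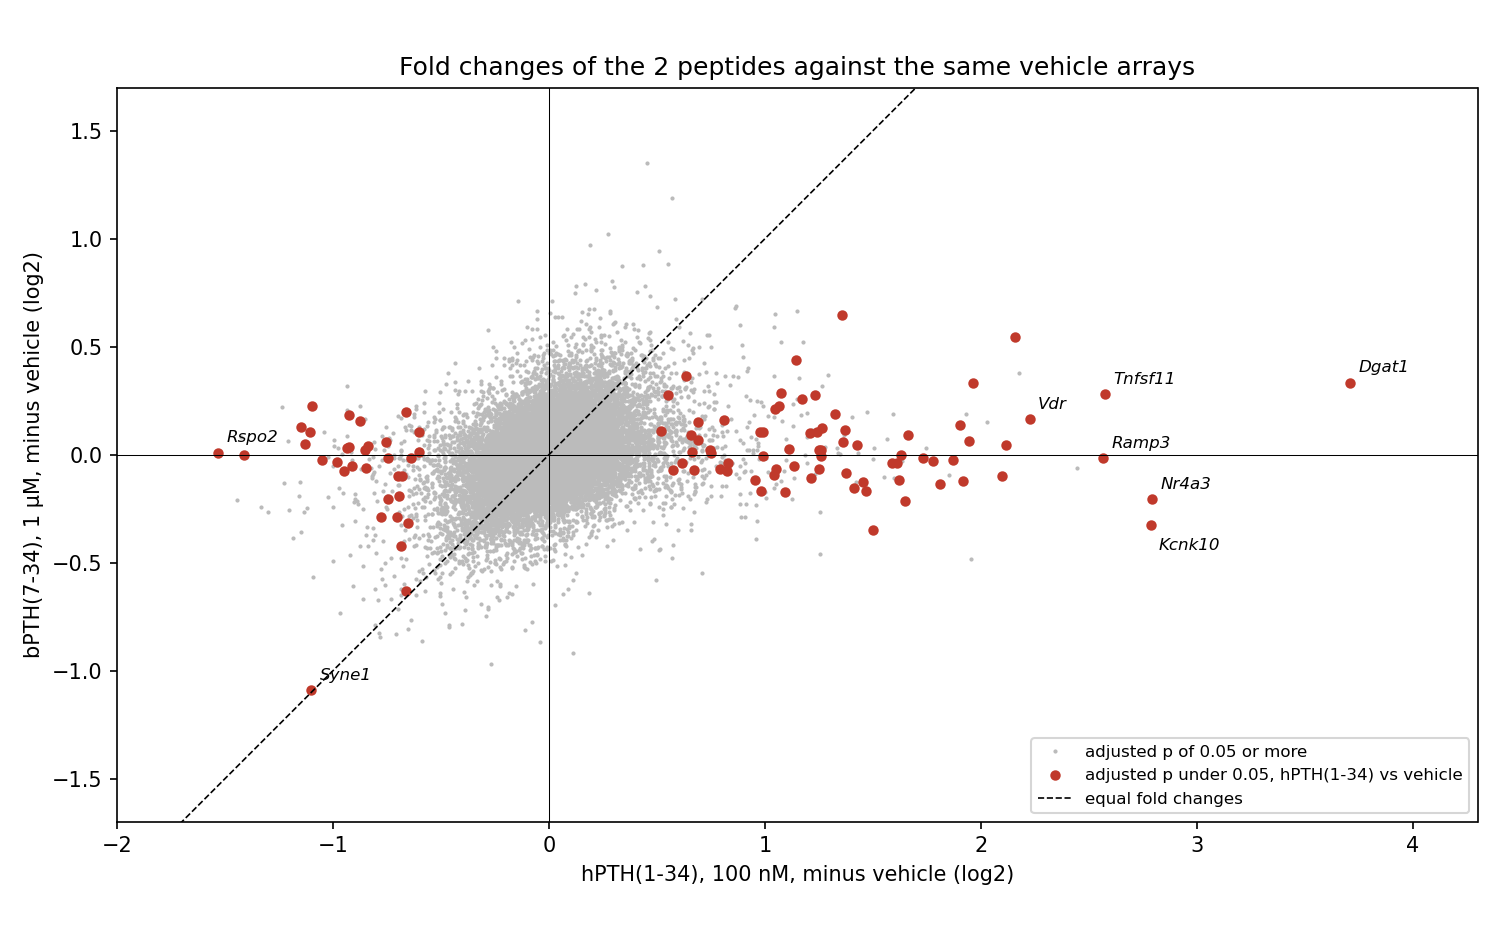
Log2 change with hPTH(1-34) (horizontal axis) against log2 change with bPTH(7-34) (vertical axis), both relative to the same 3 vehicle arrays, for 23521 clusters in grey, with the 106 called for hPTH(1-34) in red and a dashed line of equal changes. The median bPTH(7-34) change of the red points, signed by the hPTH(1-34) direction, was 0.01.

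The third comparison tested hPTH(1-34) at 100 nM directly against bPTH(7-34) at 1 µM. Dgat1 was higher with hPTH(1-34) by 3.38 ± 0.26 (SE, n = 3 per group, 10.4-fold, adjusted p = 0.00329), Nr4a3 by 3.00 ± 0.23 (adjusted p = 0.00329) and Vdr by 2.06 ± 0.22 (adjusted p = 0.0112). Kcnk10 (3.11 ± 0.42), Ramp3 (2.58 ± 0.36), Rdh10, a retinol dehydrogenase (2.44 ± 0.37), Dock9 (2.20 ± 0.25), Ugdh (2.07 ± 0.24), Gfpt2, of the hexosamine pathway (2.04 ± 0.26), and Nr4a2 (1.95 ± 0.21) were also higher, with adjusted p from 0.0112 to 0.0335. With bPTH(7-34) too, Nr4a3, Ramp3 and Kcnk10 lay little above background (1.96 ± 0.04, 1.98 ± 0.14 and 2.08 ± 0.52 SD). Rspo2 was lower (-1.54 ± 0.23), as were Lgr5 (-1.51 ± 0.25), Bmp4 (-1.41 ± 0.24), Calhm5 (-1.32 ± 0.18) and Lbh (-1.28 ± 0.15), with adjusted p from 0.0156 to 0.0488. Gpr176 (-1.21 ± 0.16), Irs1 (-1.18 ± 0.19), Swap70 (-1.14 ± 0.19), Bend5 (-1.11 ± 0.14) and Cdc42ep3 (-1.03 ± 0.11) were lower too, with adjusted p from 0.0112 to 0.0488. Vegfa (1.20 ± 0.20, adjusted p = 0.0446), Nfil3, a clock-linked repressor (0.99 ± 0.16, 0.0376), and the stress gene Ddit4 (0.99 ± 0.16, 0.0423) passed as well. Tnfsf11 differed by 2.29 (95% interval 1.32 to 3.27, adjusted p = 0.0674) and Il6 by 1.71 (0.78 to 2.64, adjusted p = 0.154), and neither passed.

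Between the peptides 109 clusters passed, 78 higher and 31 lower with hPTH(1-34), and 63 of them (52 higher, 11 lower) differed at least 2-fold. There were 2240 at an unadjusted p under 0.05. All 109 had arrays of the groups that did not overlap, as had 11.1% of all clusters (10% by chance for independent arrays). Of the 109, 80 were also called against vehicle, all in the same direction (57 higher, 23 lower), where independent lists would share 0.242 and 0.0435, but both comparisons use the same hPTH(1-34) arrays. The count was 262, 3 and 3 without hPTH(1-34) array 1, 2 and 3, and 48, 2 and 3 without bPTH(7-34) array 1, 2 and 3. Of the 34 named genes that passed, 32, 2 and 2 still passed without hPTH(1-34) array 1, 2 and 3, and 15, 2 and 2 without bPTH(7-34) array 1, 2 and 3. In each of these fits all 109 clusters, chosen on the same arrays, kept an unadjusted p under 0.05 in limma. The median size of their log2 changes ran from 1.035 to 1.185, against 1.12 with all arrays. With the array number as a block, 29 of the 34 still passed, and Bmp4, Irs1, Swap70, Ddit4 and Vcl did not (adjusted p from 0.0529 to 0.0825). A limma fit of the 6 arrays alone called 0, with 2066 at an unadjusted p under 0.05, and a fit of all 41345 clusters called 3. The moderated F-test for any difference among the 3 groups called 90 clusters, with 1924 at an unadjusted p under 0.05. That count was 59, 16 and 9 without vehicle array 1, 2 and 3, then 198, 3 and 2 without the hPTH(1-34) arrays and 49, 12 and 25 without the bPTH(7-34) arrays, in the same order. With the array number as a block it was 59, and in a fit of all clusters 2.

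Of the 24 cAMP/CREB targets 6 were higher with hPTH(1-34) than with bPTH(7-34) and 0 lower, and 8 were higher adjusted over the list alone (camera adjusted p = 9.65e-09, and adjusted p = 0.182 with an estimated correlation). Among them were Nr4a3, Nr4a2, Rgs2 (1.30 ± 0.21, adjusted p = 0.0389) and Crem (0.74 ± 0.11, adjusted p = 0.0297). Crem, at 2.07 to 2.3 with bPTH(7-34), lay little above background there too. Of the 31 receptor and cAMP feedback genes 4 were higher, Pde10a among them (1.27 ± 0.15), and 6 adjusted over the list alone (camera adjusted p = 0.0115, and adjusted p = 0.273 with an estimated correlation). That call was lost without bPTH(7-34) array 2 (adjusted p = 0.0674). In mineral and phosphate handling Vdr alone of 16 was higher, and 4 were higher adjusted over the list alone (camera adjusted p = 0.00299, and adjusted p = 0.273 with an estimated correlation). Cytoskeleton and SRF/YAP targets were lower, with Vcl (-0.61 ± 0.09) alone passing and 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 6.84e-04, and adjusted p = 0.380 with an estimated correlation). Unfolded protein and ATF4 response genes were higher as a list, with 18 of 20 positive, 0 passing and 1 higher adjusted over the list alone (camera adjusted p = 0.00360, and adjusted p = 0.273 with an estimated correlation). These medians kept their sign under both scalings. In that list Xbp1, a transcription factor of the endoplasmic reticulum stress response, gave 0.47 ± 0.11 (adjusted p = 0.158). fry called the cAMP/CREB list alone (adjusted p = 0.0140). The number of lists called, 5, was 8 without hPTH(1-34) array 1, 9 without bPTH(7-34) array 1 and 8 without bPTH(7-34) array 3.

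Lists not called between the peptides held single genes that passed. Plaur (1.64 ± 0.23) and the protease gene Adamts9 (0.92 ± 0.16) were higher in the matrix protease list, Inhba (1.32 ± 0.20) in the TGF-beta and BMP axis, Il4ra (1.23 ± 0.18) among NF-kB genes and Pmvk (1.63 ± 0.23) in cholesterol biosynthesis, with adjusted p from 0.0239 to 0.0488. Scx (-0.86 ± 0.10) and Pdk4 (-0.96 ± 0.14) were lower, with adjusted p = 0.0147 and 0.0243. Adipocyte markers, 8 of 11 positive, had camera adjusted p = 0.0568, and 0.00771 with the array number as a block, 0.0143 without bPTH(7-34) array 1, 2.60e-04 without hPTH(1-34) array 2 and 0.0237 without bPTH(7-34) array 3. Interferon response genes, 6 of 19 positive, had camera adjusted p = 0.235 towards lower levels, and 4.78e-05 without hPTH(1-34) array 1 and 0.0105 without bPTH(7-34) array 3. Wnt/beta-catenin targets, 5 of 18 positive, had 0.0649 towards lower levels, and 0.0465 and 0.0357 without bPTH(7-34) array 1 and 3. NF-kB and cytokine genes, 11 of 27 positive, had 0.777 towards lower levels, and 0.00806 without hPTH(1-34) array 1. Glycolysis genes, 16 of 21 positive, had 0.0568 towards higher levels, and 0.0207 with the array number as a block, 0.0313 without bPTH(7-34) array 1 and 0.00453 without hPTH(1-34) array 3. Cholesterol biosynthesis genes, 4 of 19 positive, had 0.0685 towards lower levels, against the direction of Pmvk, and 0.00585 without hPTH(1-34) array 1 and 0.0196 without bPTH(7-34) array 1. Hypoxia and HIF targets, 11 of 18 positive, had 0.0643 towards higher levels, and 0.0190 without bPTH(7-34) array 2 and 0.0106 without hPTH(1-34) array 3. Median and mean differed in sign for the osteoclast-regulating, matrix protease, IGF, FGF, circadian and fibroblast lists. Housekeeping genes had a median of 0.07 (camera adjusted p = 0.408).

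Across the 23521 clusters, the log2 changes with the 2 peptides had Pearson's r = 0.357 and Spearman's rho = 0.391, and 63.4% had the same sign. The comparisons share the vehicle arrays, and clusters are not independent replicates. In 100 simulated sets with unchanged groups and shared vehicle arrays, r averaged 0.501 (0.484 to 0.523), rho 0.472 and the same-sign share 66.7%. The covariance was 0.0139 in the data and 0.0137 in the simulations, a difference of 2.37e-04. These simulations leave the array number out. With the number as a block the noise covariance was 0.0105, and the data exceeded it by 0.00342. The jackknife error of r over arrays was 0.204. With the vehicle arrays split into 1 and 2, one part per peptide, no array is shared, and r over the 6 ways averaged -0.0515 (-0.148 to 0.0158), with 5 of 6 negative. This split, chosen after the data were seen, parts array numbers between the peptides, and arrays of one number correlate, which draws r down. Whether the changes are related beyond the shared vehicle arrays is left open by these values.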

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

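Of the tests given here, the one of the spread of hPTH(1-34) array 1 was chosen after its value was seen, and the pattern it tests was itself found in the data.

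Among the 17824 transcript clusters without a single gene name, which the comparisons of named genes left out, 2 passed 0.05 between hPTH(1-34) and vehicle in a fit of all 41345 clusters (adjusted p = 0.0372 each). They stand out because they passed in data outside the main measurement. Cluster 17208591 went from 3.34 ± 0.38 (SD) with vehicle to 1.25 ± 0.24 with hPTH(1-34) and 1.22 ± 0.22 with bPTH(7-34) (adjusted p = 0.303 for the latter). Its log2 changes were alike, -2.09 ± 0.22 (SE) with hPTH(1-34) and -2.12 ± 0.22 with bPTH(7-34), against the same vehicle arrays. The adjusted p differ because the adjustment depends on the other clusters of each comparison, so this fall is not particular to hPTH(1-34). Cluster 17208763 went from 2.59 ± 0.04 to 1.09 ± 0.20 with hPTH(1-34), and was 1.86 ± 0.21 with bPTH(7-34) (adjusted p = 0.884). Both with hPTH(1-34), and 17208591 with bPTH(7-34) too, lay under the background limit of 1.69, so their falls with hPTH(1-34) are known only as at least 1.65 and 0.90 on the log2 scale. The files pair neither with a gene, and no explanation was tested.

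The 106 clusters called for hPTH(1-34) moved less in the arrays numbered 1 than in the other numbers, by a median of 0.45 (0.39 to 0.60) on the log2 scale. Vehicle RNA mixed into hPTH(1-34) sample 1 in a single share predicts one linear response share for all genes. The share of number 1 was 0.527 for rising and 0.672 for falling genes, a difference of -0.145 (-0.253 to -0.0717), against that prediction. Mixing is not excluded by this. The prediction needs an unshifted vehicle array 1 and values linear in RNA, and the genes were chosen by their change on these arrays. A compressed range on hPTH(1-34) array 1 stays open, since RMA gives all arrays nearly one range and the interquartile ratio of 1.04 to the other arrays decides nothing. Levels already shifted in vehicle array 1 stay open as well: that array lay 0.18 (0.14 to 0.25) towards the hPTH(1-34) level, against 0.23 for an even share of the shortfall, while hPTH(1-34) array 1 lay 0.25 (0.20 to 0.38) short. No biological explanation was tested, since the labels name no difference between the numbers. Cells were prepared independently for each replicate, but whether arrays of one number share a preparation is not stated.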

How the results depend on the processing

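The filter at a mean log2 of at least 3 and the split of the vehicle arrays were chosen after seeing the data, and the other alternatives before. No named gene that passed reversed direction in the alternatives run. Without single arrays this follows from groups that do not overlap. The block, the trended eBayes and the filter leave a gene's change as it is, so they could not reverse it. No list reversed either, but a reversal was counted only where both fits called the list. None could therefore be counted with an estimated correlation, and mixed fry gives no direction. For hPTH(1-34) against vehicle (106), hPTH(1-34) against bPTH(7-34) (109) and the F-test (90), the counts were 16, 3 and 2 with all clusters, where more clusters are tested, 182, 211 and 170 with a mean log2 of at least 5, and 166, 204 and 157 with array weights. The first 2 were 186 and 215 with a mean log2 of at least 3, 60 and 63 with at least 2-fold, and 0 and 0 in limma on the 6 arrays alone, where fewer arrays give the spread (1936 and 2066 at an unadjusted p under 0.05). Without single arrays they ranged from 0 to 259, from 2 to 262, and for the F-test from 2 to 198. The cause of these changes in the counts was not tested.

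The array number as a fixed block gave 112 (74 of the 106 shared), 116 (78 of the 109 shared) and 59 by the F-test. Of the named genes that passed, 22 of 31 and 29 of 34 kept their call with it, 30 and 32 with quantile normalisation, and 31 and 34 with the median shift. Of 9 pairs with the same number, 6 correlated above 0.1 after group means were removed (0.0646 to 0.364) and 8 of 9 arrays correlated best with their own number. In 5144 bright clusters 8 of 9 pairs did (0.0696 to 0.601), with 6 of 9 arrays. There all 3 pairs of hPTH(1-34) with vehicle (lowest 0.196) and with bPTH(7-34) (lowest 0.139) did, so a check by comparison on those clusters would have made the number a block for both, while over all clusters 2 of 3 did in each comparison. The count for bPTH(7-34) against vehicle was 0 in limma in each alternative run (780 at an unadjusted p under 0.05 in the fit of 9 arrays).

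Lists called for hPTH(1-34) against vehicle (6) were 0 with an estimated correlation, 3 by fry and 18 by mixed fry, and between the peptides (5) 0, 1 and 20, with 8 or 9 in 3 of the fits without an array. For bPTH(7-34) 1 list was called with the block (interferon response), and 0 to 6 without single arrays. The block added NF-kB genes for hPTH(1-34), and glycolysis and adipocyte markers between the peptides. The correlation of the peptides' changes was 0.239 with a mean log2 of at least 5, and 0.301 to 0.520 without single arrays. It was -0.0515 with the vehicle arrays split so that none is shared. With the block it was 0.357, an outcome fixed in advance. Each group holds every array number, so the block leaves the group differences as they are. The median signal was under 2 on the log2 scale on every array, and the filters on dim clusters gave the higher counts above.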

Other observations

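The 4 gene lists of the first paragraphs, the genes named from them and the test of 3 arrays against the other 6 were chosen after seeing the data, while the other tests of splits were planned.

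Of 63 measured genes of ribosome biogenesis, 7 were among the 250 clusters with the smallest p for hPTH(1-34) against vehicle, and 2 rose and 0 fell past the threshold. Gnl2, a GTPase of large subunit assembly, rose by 1.07 ± 0.11 (SE, n = 3 per group, limma adjusted p = 0.0105), and Ftsj3, an rRNA methyltransferase, by 0.69 ± 0.11 (adjusted p = 0.0449), both chosen after their values were seen. In the 56 members outside those clusters, 52 were positive, with a median of 0.35 (bootstrap 0.29 to 0.42), or 0.31 after quantile normalisation and 0.34 after the median shift. camera gave adjusted p = 3.87e-19, but adjusted p = 0.0671 with an estimated correlation of 0.199, and fry gave adjusted p = 0.0151. A rise of the list as a whole may underlie this, and it stays open, since the estimated correlation leaves it short of the threshold. Moreover, the 56 members were measured on the same arrays as the 7 that prompted the list. Genes of a list can move together, so these p values are no independent support. The same limit holds for the other lists below.

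Among genes of nucleotide sugar and glycosaminoglycan synthesis, Ugdh (2.12 ± 0.24), Uap1 (1.95 ± 0.23), Gfpt2 (1.92 ± 0.26) and Chst11 (1.96 ± 0.31) rose out of 39 measured. The members outside the 250 clusters had a median of 0.052 (-0.11 to 0.13), or 0.017 after quantile normalisation, with camera adjusted p = 0.540, and adjusted p = 0.722 with an estimated correlation. A list of triglyceride and fatty acid genes held synthesis genes but also genes of triglyceride breakdown, such as Pnpla2, Lipe, Mgll and Abhd5. In it 4 of 30 rose, Dgat1, Acsl4 (1.59 ± 0.20), Abhd5 (1.21 ± 0.11) and Scd1 (1.06 ± 0.18), so the list does not stand for synthesis alone. Its members outside the 250 clusters had a median of 0.10 (0.06 to 0.27), or 0.066 after quantile normalisation. They had camera adjusted p = 0.0509, and adjusted p = 0.413 with an estimated correlation. In the NRF2 antioxidant response 2 of 23 rose, Srxn1 (1.46 ± 0.20) and Txnrd1 (0.83 ± 0.11), and the remaining members had a median of 0.07 (0.02 to 0.20), or 0.032 after quantile normalisation, with camera adjusted p = 0.113, and adjusted p = 0.722 with an estimated correlation. Whether these 3 lists rise as a whole stays open. Their members were called in the comparison of hPTH(1-34) and vehicle, so the dependence of that count on single arrays applies to them too.

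Other splits of the arrays were counted for each number of calls. In the 6 arrays of each pair of groups, 10 of 10 splits into 3 and 3 gave as many calls as the real one in a fit of those arrays, for each of the 3 comparisons, since the real count was 0 and the highest other 0. At an unadjusted p under 0.05 limma gave 1936 clusters for hPTH(1-34) against vehicle, with 1487 in the highest other split, 661 for bPTH(7-34) against vehicle (1624) and 2066 between the peptides (1735). With 10 splits no share under 0.05 can be had. For the F-test, 7 of 100 drawn regroupings (of 280 possible, the real one included) gave at least the 90 real calls, and the highest other gave 174, so chance is not excluded by that test. Of the 6 others, 5 kept the 3 hPTH(1-34) arrays together, as did no further drawn regrouping, and the sixth, with 96 calls, put the arrays numbered 1 together. The regrouping by array number alone gave 62, which points to a structure of the samples by number beside that by hPTH(1-34), and the blocked F-test count was 59. Setting 3 arrays against the other 6, which pools vehicle with bPTH(7-34), the 3 hPTH(1-34) arrays gave 320 calls, as many as 1 of 84 choices, the real one. The highest other choice, the arrays numbered 1, gave 94. This test was prompted by the regroupings that kept the hPTH(1-34) arrays together and restates them, so it does not settle by itself what the planned tests left open.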
